A study of Mus musculus with 10 samples.

How the data were processed

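RAW264.7 cells, a mouse monocytic cell line that behaves like macrophages, were profiled by RNA sequencing in 5 groups of 2 libraries, 10 libraries in all. The groups were untreated control cells, cells given 100 U/ml interferon-γ (IFN-γ), IFN-γ-treated cells infected with Toxoplasma gondii strain NTE at a multiplicity of infection of 6, IFN-γ-treated cells given 2 µM MS-275, and IFN-γ-treated cells given both MS-275 and parasites. MS-275 (entinostat) is an inhibitor of class I histone deacetylases, and T. gondii is an obligate intracellular parasite that interferes with the host cell response to IFN-γ. All libraries were taken 24 h after infection, per the labels. The control label names no vehicle, so IFN-γ is compared with control together with whatever vehicle the other groups received. The series design describes the libraries of a group as biological replicates.

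Libraries were made with the TruSeq RNA kit and sequenced on a HiSeq2000, per the labels' protocols. The submitters' processing notes list CASAVA 1.8.2, FastQC 0.10.0, STAR 2.3.0, SAMtools 1.2, HTSeq 0.6 and DESeq2 1.8.1, and the genome build mm10. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited count table holds whole-number read counts per gene, with no normalization, for 38355 genes, of which 22901 had at least 1 count. In it, 1403 genes carry an identifier with no symbol, and these have no name here either. They took 0.187% to 2.49% of the counts of a library. No column belonged to other samples (0 such columns). Among the 139 genes that the naming rule picks, 45 overlap an annotated gene on the opposite strand and 18 on the same strand in GENCODE M21 on GRCm38, which is the mm10 assembly. Because the strand setting is unknown, reads of opposite-strand pairs cannot be told apart. For same-strand pairs, such as Xirp1 with Cx3cr1 and Igtp with Irgm2, a strand setting would not separate the reads either. The interferon-induced GTPases, the Ly6, Slfn and H2 genes belong to families of similar sequence, and how reads shared between relatives were counted is not given, so single members of these families are uncertain.

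The authors also deposited tables of candidate genes for 2 of the comparisons, IFN-γ against control and MS-275 plus IFN-γ against IFN-γ. Per the file headers these hold log2 fold changes and adjusted p-values by the authors, as deposited. They further hold normalized counts, a signal that the authors scaled per library: each deposited value equalled the raw count divided by 1 size factor per library, with the largest relative deviation at 5.07e-10 over genes with at least 10 counts. These tables were used for one comparison of call lists only.

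Total counts ran from 16954635 in MS-275 plus IFN-γ plus T. gondii replicate 1 to 30675148 in control replicate 1. The most abundant gene took between 0.853% and 2.99% of a library. Replicates correlated across genes with a Pearson coefficient of 0.967 to 0.991 on the log2 CPM scale. The chi-square statistic of the replicate counts exceeded its degrees of freedom by 55.5 to 139 times, so no pair differed by sampling noise alone. Intervals and floors given with single genes cover counting error only, since reads were counted without molecular identifiers.

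Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), leaving 13890. Libraries were scaled by the TMM method. Counts of all 10 libraries were fitted in 1 edgeR 4.0.16 quasi-likelihood model with 1 mean per group and 5 residual degrees of freedom (R 4.3.3), and 6 contrasts were tested with Benjamini-Hochberg adjustment at an adjusted p of 0.05, with no minimum fold change. Log2 fold changes are given ± standard error (SE), obtained from the fold change and its F statistic. The contrasts were IFN-γ against control, infection without and with MS-275, MS-275 in uninfected and in infected cells, and the difference between both MS-275 effects. CPM values were computed by edgeR on the TMM-scaled library and are given as mean ± SD of 2 libraries. Where 1 group had 0 counts, the fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio with an exact 95% binomial interval was computed.

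Replicate numbers run from 1 to 2 in every group, and the file headers place each replicate 1 library in 1 pool and each replicate 2 library in another. The deviations of same-numbered libraries from their group means correlated at 0.354 to 0.604 across genes in each of the 10 pairs of groups, and the component with 6.88% of the variance separated the numbers. The number was therefore taken to mark a shared pool. The model without a block is the main one, as fixed beforehand, and the model with the replicate number as an additive block (4 residual degrees of freedom) is given beside a result where it changes the call or moves a count by more than 1.5 times. Every gene called without the block in the 6 contrasts was also called with it.

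Gene lists were 24 in number, written before the data were examined. They covered IFN-γ-inducible GTPases, MHC class II and class I genes, interferon signalling, antiviral interferon-stimulated genes, chemokines and cytokines, antimicrobial effectors, costimulation, histone deacetylases, histone deacetylase inhibitor response, cell cycle, cholesterol synthesis, glycolysis and hypoxia, stress response, early NF-κB targets, lysosome and autophagy, alternative activation, myeloid identity, apoptosis, markers of fibroblasts, lymphoid cells, epithelial cells and dendritic cells, and RNA quality. In all 21 list members had no matching symbol and were not analysed here. Lists with at least 5 measured members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, over 132 tests with Benjamini-Hochberg adjustment. With an inter-gene correlation estimated from the residuals, 0 of the 132 list tests passed, against 56 with the preset value, so each list test below is given with both adjusted p-values.

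Genes named in the text follow a rule fixed beforehand: the 5 with the largest rise and the 5 with the largest fall in a comparison among called genes with a mean log2 CPM of at least 1 and no overlap between the replicates of both groups, leaving out Gm numbers, Rik, Mir and Snor symbols and pseudogenes with -ps in the symbol, up to 2 per direction of each list described, a fixed set of IFN-γ and histone deacetylase genes, the members of the class raised by MS-275 after infection had lowered them, and the interaction genes. Pseudogenes with other symbols were not left out. Some genes that the rule picks are not reported here. Expected overlaps of calls were computed as the product of list lengths over the genes tested. Within the set induced by IFN-γ the product was taken over the induced genes instead. In 20 simulated data sets neither infection nor MS-275 changed any gene. They gave the number of calls and the covariance of fold changes expected with no effects. Another 20 held the IFN-γ and infection effects and no MS-275 effect. Neither kind held a pool effect.

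The edgeR step was tested on simulated counts for MS-275 plus IFN-γ against IFN-γ, with 50 changed genes per fold size and 12472 genes tested. Without a pool effect the model recovered 2 of 50 genes changed 1.5-fold, 4 of 50 changed 2-fold, 42 of 50 changed 4-fold and 47 of 50 changed 8-fold, with 4 false calls. The simulation held 13690 unchanged genes, but those that failed the count filter were not tested and could not be called. With a simulated pool effect and 12475 genes tested it recovered 0 of 50 at 2-fold, 12 of 50 at 4-fold and 31 of 50 at 8-fold without the block, and 4, 39 and 47 of 50 with it. DESeq2, run without a block or a pool effect, recovered 5, 19, 47 and 48 of 50 at 1.5-, 2-, 4- and 8-fold, with 26 false calls. In the data 2980 genes were called for this contrast, and with fewer changed genes the adjusted threshold is stricter. The simulated pool effect was added to dispersions from the model without a block, which already hold variation between pools. The recovered shares therefore do not carry over to the data.

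Alternatives fixed beforehand were DESeq2 1.42.0, DESeq2 size factors (RLE) or upper-quartile normalization in edgeR, no filter on low counts, a filter of at least 5 CPM in 2 samples, only the libraries of the groups compared, the replicate block, an adjusted p of 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. One more, leaving out the first library of both infected groups, was chosen after seeing the data. Parasite transcripts were not analysed here.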

Results

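Gene expression was measured by RNA sequencing in 10 libraries of mouse RAW264.7 cells, in 5 groups of 2 libraries. The groups allow 6 comparisons: IFN-γ against control, T. gondii infection in IFN-γ-treated cells without and with MS-275, MS-275 in uninfected and in infected IFN-γ-treated cells, and the difference between both MS-275 effects. Total counts per library were 30675148 and 23930537 in control cells, 24328627 and 23627725 with IFN-γ, 25368416 and 21423303 with IFN-γ and T. gondii, 23381038 and 19138300 with MS-275 and IFN-γ, and 16954635 and 20906978 with all of these. Adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 13890 genes, n = 2 libraries per group, and a gene is called, or said to rise or fall, at an adjusted p under 0.05. List tests are by limma camera. Log2 fold changes are given ± SE. The first component of the libraries held 56.1% of the variance and the next 18.4%. Gene positions are from the GENCODE M21 annotation of GRCm38 (mm10).

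**Figure D1:**
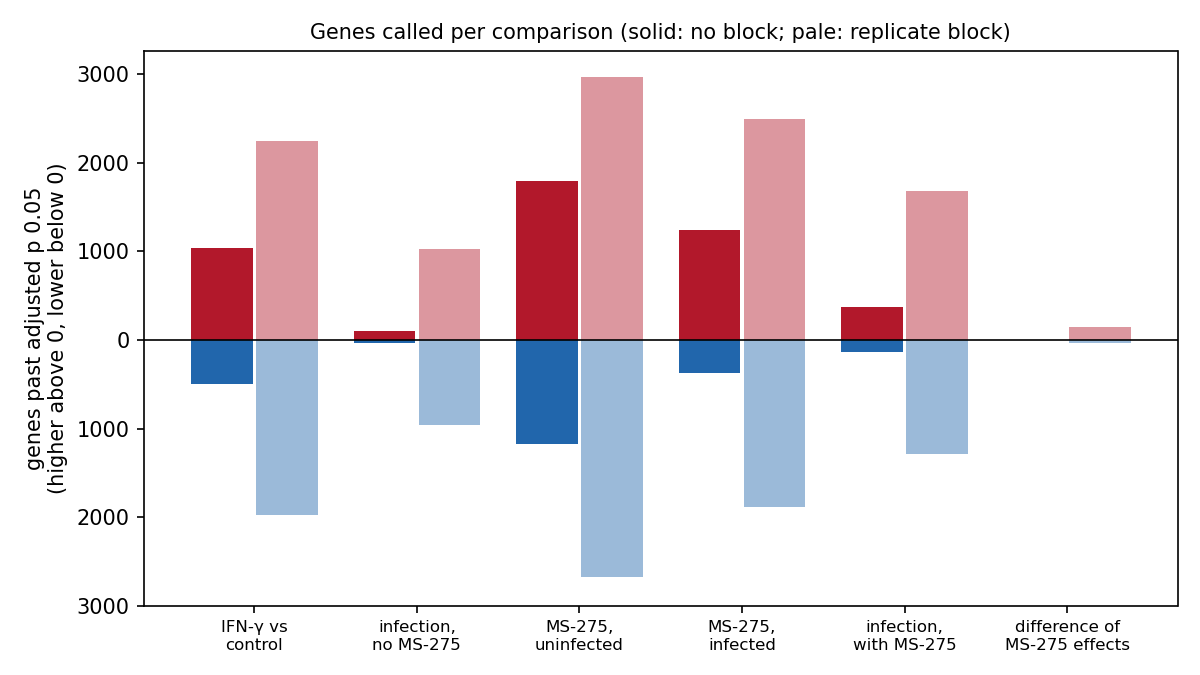
Number of genes called at an adjusted p of 0.05 in each of the 6 comparisons, higher and lower, by the edgeR model without (solid) and with (pale) the replicate block. The counts run from 1 gene for the difference between both MS-275 effects to 2980 genes for MS-275 in uninfected cells without the block. With the block they run from 181 to 5652 for the same comparisons.

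The comparison of IFN-γ with control asks which genes the cytokine changes in these cells. The immunity-related GTPases and guanylate-binding proteins, which act on the vacuole of intracellular parasites, rose together. Of 22 measured members 20 rose and 0 fell (20 adjusted over the list alone), with a median log2 fold change of 9.92, or 9.89 with a member at 0 counts set to its bound. Iigp1 rose by 11.11 ± 0.77 (adjusted p = 1.64e-04) and Gbp2 by 10.26 ± 0.86. Igtp (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591) rose from 3.41 ± 0.887 to 822 ± 110.1 CPM (mean ± SD, n = 2), a log2 fold change of 7.92 ± 0.97. Irgm1 (ENSMUSG00000046879, chromosome 11, 48861968 to 48871683), a regulator of these GTPases, rose by 5.62 ± 0.73. The list test gave an adjusted p of 1.30e-27, and adjusted p = 0.337 with an estimated correlation.

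Antigen presentation genes were also higher with IFN-γ. In the MHC class II list 9 of 16 members rose (10 adjusted over the list alone). Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), the master activator of MHC class II transcription, rose by 9.02 ± 0.55 (adjusted p = 1.13e-04), H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) by 7.997 ± 1.345 and H2-DMb1 by 8.20 ± 1.36. The class II list test gave an adjusted p of 1.93e-06, and adjusted p = 0.566 with an estimated correlation. Of 22 class I and immunoproteasome genes 16 rose (21 adjusted over the list alone), among them the peptide transporter gene Tap1 (4.34 ± 0.55) and H2-T24 (5.41 ± 0.54). For class I the list test gave an adjusted p of 9.95e-14, and adjusted p = 0.434 with an estimated correlation.

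All 40 measured antiviral interferon-stimulated genes rose (40 adjusted over the list alone), with Ifi44l at 10.15 ± 0.46 and the nucleic acid sensor gene Zbp1 at 9.86 ± 0.43. Of 25 interferon signalling genes 16 rose (17 adjusted over the list alone). They included the transcription factor gene Irf1 at 5.96 ± 0.78, and the feedback inhibitors Socs1 at 9.03 ± 0.72 and Usp18 at 7.21 ± 0.54. The list tests gave adjusted p-values of 1.39e-43 for the antiviral and 1.58e-12 for the signalling genes, and adjusted p = 0.337 and 0.420 with an estimated correlation.

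Among 32 chemokine and cytokine genes 15 rose and 1 fell (16 and 1 adjusted over the list alone). The T cell attractants Cxcl9 and Cxcl10 rose by 9.93 ± 0.75 and 9.13 ± 0.73, and Ccl3 changed by -1.33 ± 0.34. Of 26 antimicrobial effectors 10 rose and 0 fell by edgeR (10 higher adjusted over the list alone, 1 lower with the block). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose from 3.68 ± 1.44 to 323 ± 52.3 CPM (mean ± SD, n = 2), a log2 fold change of 6.46 ± 0.70, and the tryptophan-degrading enzyme gene Ido1, at 0 counts in control cells, was at least 182-fold higher. Of 20 costimulation genes 12 rose (12 adjusted over the list alone, with 1 lower, as with the block), including Slamf8 (9.73 ± 0.99) and Cd274, which encodes the checkpoint ligand PD-L1 (4.87 ± 0.53). Their list tests gave adjusted p-values of 7.76e-09, 2.87e-06 and 6.05e-07 in this order, and adjusted p = 0.431, 0.485 and 0.420 with an estimated correlation.

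Smaller parts of other lists moved with IFN-γ. Of 32 early NF-κB targets 8 rose and 1 fell (18 and 2 adjusted over the list alone, replicate block 19 and 2), with Ptgs2 at 5.97 ± 0.41 and Zfp36 at 2.64 ± 0.40. In the stress response list 5 of 27 members rose (6 adjusted over the list alone, replicate block 10), including Nupr1 (2.94 ± 0.58) and Trib3 (2.86 ± 0.64). Of 33 myeloid identity genes 11 rose and 2 fell (14 and 5 adjusted over the list alone, replicate block 15 and 7). Ly6c1 was 224-fold (95% counting interval 39.7 to 8906) higher, while the fractalkine receptor gene Cx3cr1 changed by -3.40 ± 0.31 and Tlr2 by -1.80 ± 0.20. In the cell cycle list 2 of 45 members fell (0 adjusted over the list alone, replicate block 21 with 1 higher), namely Prc1 (-1.10 ± 0.26) and Tyms (-0.85 ± 0.22). Among markers of other cell types Clec9a (8.32 ± 0.62) and Xcr1 (4.75 ± 0.66), known from dendritic cells, were higher and Cd24a (-2.49 ± 0.33) was lower (2 higher and 1 lower of 9, 3 and 1 adjusted over the list alone, replicate block 4 and 1), and the T cell kinase gene Lck (2.04 ± 0.27) was higher. The histone deacetylase inhibitor response list had 3 higher members of 22 (3 higher and 1 lower adjusted over the list alone, replicate block 7 higher and 4 lower, list test adjusted p = 0.333), led by the tubulin gene Tubb3 (5.39 ± 0.47). The list tests of NF-κB, stress, myeloid, cell cycle and dendritic genes gave adjusted p-values of 6.75e-05, 0.00310, 0.0129, 9.44e-04 and 0.0189, and adjusted p = 0.566, 0.337, 0.640, 0.778 and 0.431 with an estimated correlation.

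Among called genes with a mean log2 CPM of at least 1 and no overlap between the replicates of both groups, and leaving out symbols that are Gm with a number or end in Rik, the rule picked the 5 with the largest fitted rise: Ly6i (at least 303-fold), Sectm1a (11.42 ± 1.13), the serpin gene Serpina3g (11.31 ± 0.77), Dpy19l3 (at least 266-fold) and Ly6a (11.12 ± 1.08). Ly6i and Dpy19l3 had 0 counts in control cells, so their rank rests on the fit and is not established. Its picks with the largest fitted falls were Cd300e, which was lower 50.6-fold (95% counting interval 17.1 to 247), the DNA repair gene Xrcc5 (-5.58 ± 0.57, a value that rests on 2 and 7 raw counts with IFN-γ and is uncertain), the chemokine receptor gene Cxcr4 (-4.65 ± 0.53), Xirp1 (-4.48 ± 0.89) and Cd33 (-4.32 ± 0.73). Xirp1 lies within Cx3cr1 on the same strand, so whether its fall is separate from that of Cx3cr1 is uncertain. In all 1542 genes were called, 1045 higher and 497 lower, of which 878 and 326 changed at least 2-fold (1178 and 701 with the block). With the replicate block 4230 were called, 2254 higher and 1976 lower (67.8% higher without and 53.3% with the block), and DESeq2 called 2383. Without control replicate 1 or 2 the count was 455 or 593, and without IFN-γ replicate 1 or 2 714 or 718. Of the 45 called genes named here 11 lost their call when some library was left out: Ly6i, Xirp1, Cd33, H2-Aa, H2-DMb1, Ccl3, Zfp36, Prc1, Tyms, Nupr1 and Trib3.

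**Figure D2:**
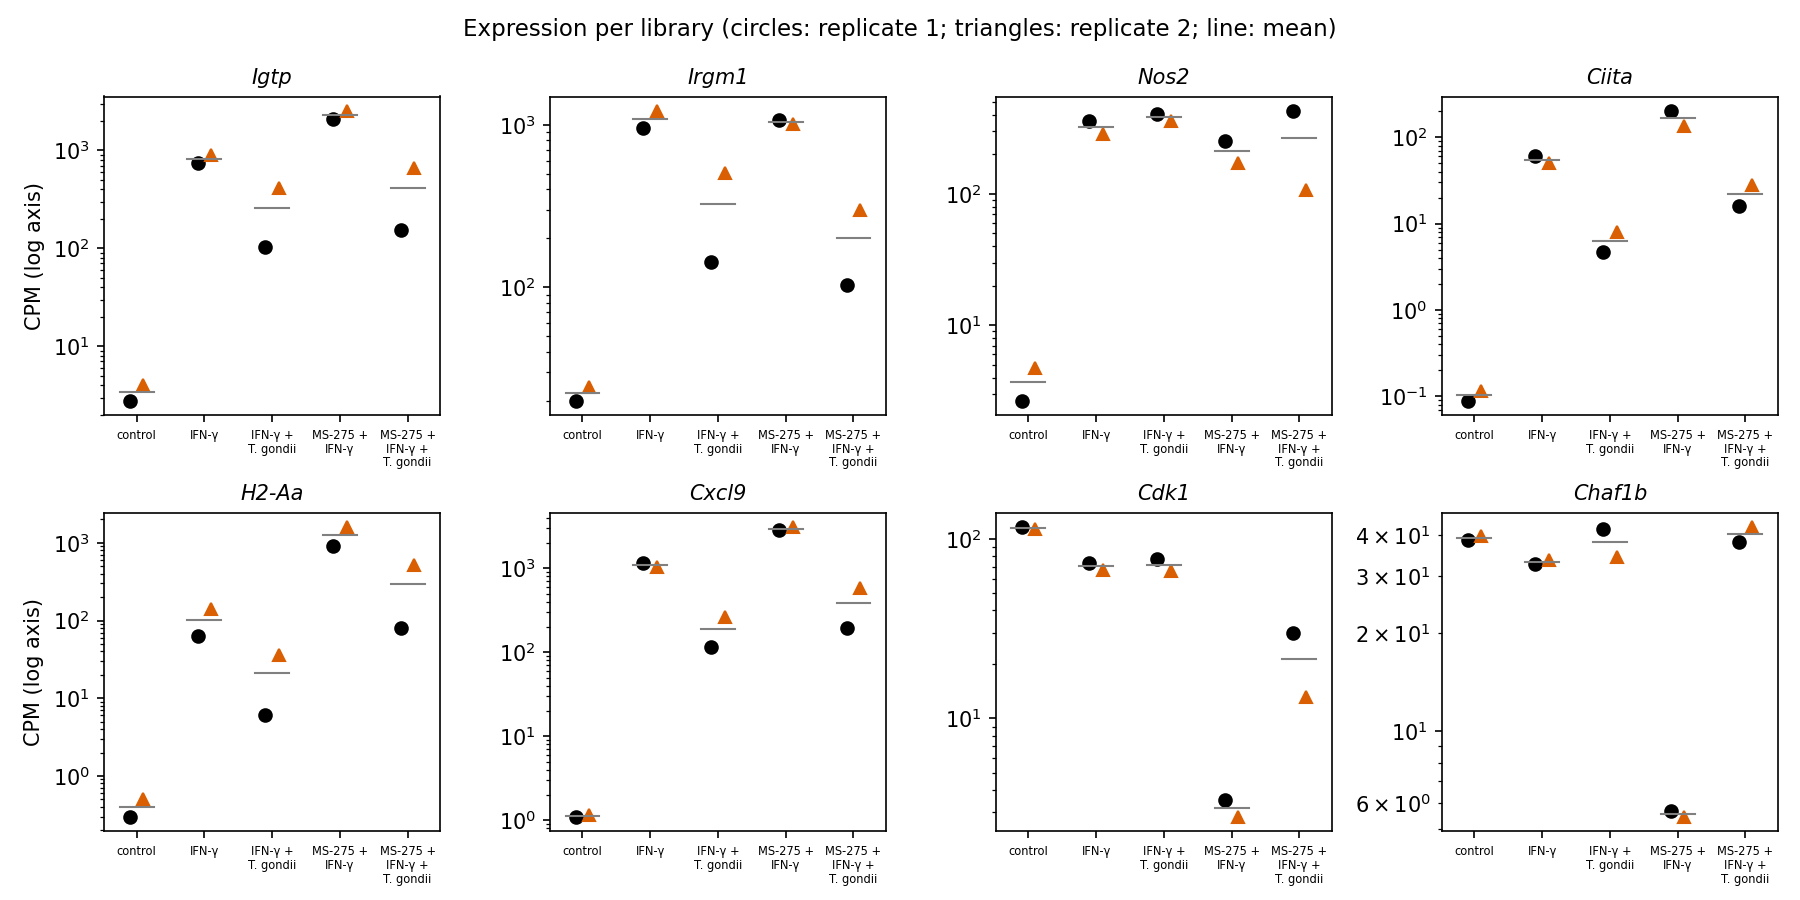
CPM of 8 genes in each library (log axis), by group, with circles for replicate 1, triangles for replicate 2 and a line at the group mean. Igtp, Irgm1, Ciita and H2-Aa sit lower in replicate 1 of both infected groups, and Cdk1 is lowest with MS-275 in uninfected cells. Igtp and H2-Aa also sit lower in replicate 1 of both uninfected IFN-γ groups, and Irgm1 in the one without MS-275.

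Infection of IFN-γ-treated cells asks how the parasite changes the activated state. Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), the gene of the growth factor GM-CSF, was at 0 counts with IFN-γ alone and reached 22.5 ± 7.71 CPM (mean ± SD, n = 2) in infected cells, at least 348-fold higher. Ciita changed by -3.13 ± 0.37 (adjusted p = 0.0153), from 55.2 ± 6.76 to 6.34 ± 2.26 CPM. Of 32 chemokine and cytokine genes 5 rose and 0 fell (17 and 3 adjusted over the list alone, replicate block 15 and 3), with the inflammatory cytokine gene Il1b at 3.75 ± 0.68. Of 40 antiviral genes 5 rose (10 adjusted over the list alone, replicate block 15 with 2 lower), among them Rsad2 (3.26 ± 0.56) and Mx2 (2.98 ± 0.39). These lists gave adjusted p-values of 6.14e-06 and 9.58e-05, and adjusted p = 0.494 and 0.640 with an estimated correlation.

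The IFN-γ-inducible GTPases had a lower median level in infected cells, with no single member called over all genes by edgeR. The count of called members was 0 of 22, and 15 were lower adjusted over the list alone and 20 with the replicate block. Their median log2 fold change was -1.66, with a list test adjusted p of 1.58e-12, and adjusted p = 0.431 with an estimated correlation. Igtp had 257 ± 217 CPM, a log2 fold change of -1.68 ± 0.73 (adjusted p = 0.297, and 0.0273 with the block). The values were -1.74 ± 0.61 for Irgm1 (adjusted p = 0.199, block 0.0216) and -1.53 ± 0.59 for Gbp2 (adjusted p = 0.234, block 0.0254). H2-Aa had -2.27 ± 0.98 (adjusted p = 0.291, block 0.00970). Nos2 had 382 ± 29.2 CPM and a log2 fold change of 0.24 ± 0.55 (adjusted p = 0.893), and Cxcl10 one of 0.53 ± 0.50 (adjusted p = 0.673), neither called with the block.

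In the MHC class II list 1 of 16 members, Ciita, was lower (1 adjusted over the list alone, replicate block 9), with a median of -1.30, or -1.05 without a member at or under the floor in both groups. In the class I list 1 of 22 was lower (1 adjusted over the list alone, replicate block 11), Nlrc5, an activator of class I transcription (-1.38 ± 0.23). Of 32 early NF-κB targets 3 rose (7 adjusted over the list alone, with 2 lower, replicate block 10 and 4), including Myc (4.37 ± 0.48) and Egr2 (1.92 ± 0.31). The alternative activation list had 1 higher member of 12, the chemokine gene Ccl24 (25.1-fold (95% counting interval 8.29 to 124)), with 4 higher and 1 lower adjusted over the list alone, and 4 and 1 with the replicate block. In the myeloid list 1 of 33 rose, Tlr2 (1.14 ± 0.20), and 1 fell, Ly6c1 (-4.41 ± 0.80), with 3 and 5 adjusted over the list alone and 3 and 7 with the block. These 5 list tests gave adjusted p-values of 5.10e-05, 3.53e-05, 0.0189, 0.0150 and 0.0129, and adjusted p = 0.597, 0.640, 0.703, 0.550 and 0.640 with an estimated correlation. With the block the alternative activation test gave 0.0652. Another 3 lists had a list test below 0.05: interferon signalling (adjusted p = 0.00576, 0.640 with an estimated correlation), cell cycle (0.0113 and 0.833) and cholesterol synthesis (0.0436 and 0.876, block 0.0662). The edgeR count of called members was 0 in each. With the block it was 3 higher and 8 lower in interferon signalling, 8 lower in cell cycle and 0 in cholesterol synthesis, and adjusted over the list alone 2 higher and 7 lower, 5 lower and 0. The antimicrobial list passed its list test only with the block (adjusted p = 0.0427, against 0.0534 without it and 0.773 with an estimated correlation). Of its members edgeR called 0 (1 higher and 2 lower adjusted over the list alone, replicate block 1 and 6).

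Other large rises were those of the matrix genes Fbln5 (7.40 ± 1.24) and Tnc (5.33 ± 0.86), the muscle actin gene Acta1 (198-fold (95% counting interval 35.1 to 7840)) and Xrcc5 (5.75 ± 0.57, uncertain because it rests on the same 2 and 7 counts with IFN-γ alone). The size of the Fbln5 rise is uncertain too. Its raw counts were 3 and 1 with IFN-γ alone and 726 and 84 in infected cells. Other large falls were those of Rnase6 (-2.76 ± 0.46), Clec9a (-2.75 ± 0.46) and the focal adhesion gene Zyx (-2.73 ± 0.42). In all 135 genes were called, 99 higher and 36 lower, and 95 and 33 changed at least 2-fold (537 and 318 with the block). The replicate block gave 1987 calls, 1031 higher and 956 lower (73.3% higher without and 51.9% with the block), DESeq2 called 955, and edgeR on these groups alone called 0, with 1541 at an unadjusted p under 0.05. The count was 1 without IFN-γ replicate 1 or 2, 8 and 521 without replicate 1 and 2 of the infected group, 41 without control replicate 1 or 2, 38 and 35 without replicate 1 and 2 of MS-275 plus IFN-γ, and 78 without replicate 2 of MS-275 plus IFN-γ plus T. gondii. Csf2 kept its call without each library, and the other 17 called genes named here lost it without some library.

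MS-275 in uninfected cells asks what the inhibitor does to the IFN-γ response itself. Cell cycle and replication genes fell: 44 of 45 members were lower (45 adjusted over the list alone), with a median log2 fold change of -3.57. Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938), the mitotic kinase, went from 70.3 ± 4.39 to 3.18 ± 0.493 CPM (mean ± SD, n = 2), a log2 fold change of -4.46 ± 0.38 (adjusted p = 6.05e-04), and the replication helicase gene Mcm5 changed by -4.55 ± 0.52. The falls of Shcbp1 (-5.30 ± 0.62), Lrr1 (-5.24 ± 0.88), Pbk (-4.93 ± 0.68) and the DNA repair gene Exo1 (-4.93 ± 0.53) were among the 5 largest picked in the same way. The list test gave an adjusted p of 1.30e-27, and adjusted p = 0.431 with an estimated correlation.

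Some MHC class II genes rose further with MS-275. Of 16 members 5 were higher (8 adjusted over the list alone, replicate block 12 with 2 lower), and H2-Aa went from 101 ± 54.4 to 1248 ± 481 CPM, a log2 fold change of 3.62 ± 1.03 (adjusted p = 0.0378). H2-Oa rose by 2.75 ± 0.39 and Ciita by 1.61 ± 0.34 (adjusted p = 0.0123). Chemokine and cytokine genes had 6 higher and 1 lower members of 32 (6 and 1 adjusted over the list alone, replicate block 11 and 2), with Ccl5 at 5.59 ± 0.56, Il1a at 4.94 ± 0.87 and Il27 at -2.06 ± 0.49. Costimulation genes had 4 higher and 1 lower members of 20 (5 and 1 adjusted over the list alone, replicate block 10 and 2), with Cd86 at 5.05 ± 0.51, Havcr2 at 1.63 ± 0.18 and Tnfsf9 at -0.88 ± 0.21. The 3 list tests gave adjusted p-values of 0.00996, 0.0436 (block 0.0662) and 0.0413 (block 0.0532), and adjusted p = 0.752, 0.767 and 0.640 with an estimated correlation. The GTPases had 1 called member of 22 (1 adjusted over the list alone, replicate block 7). Nos2 had a log2 fold change of -0.61 ± 0.55 (adjusted p = 0.491).

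Listed markers of other lineages moved in both directions with MS-275, more of them higher than lower, and some alternative activation genes were higher. Of 71 listed markers 32 passed the count filter, which keeps a gene that is silent without MS-275 only because other libraries express it. On the 6 libraries without MS-275 alone 18 passed, of which 8 rose and 2 fell with MS-275 in uninfected cells and 5 rose and 1 fell in infected cells. Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), a surface marker of T cells and fibroblasts, was higher 641-fold (95% counting interval 177 to 5299). Of 13 fibroblast markers 6 rose (8 adjusted over the list alone), including Thy1 and Cav1 (167-fold (95% counting interval 29.4 to 6622)), with a median of 2.82, or 1.38 with bounds. Of 6 lymphoid markers 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Cd5 72.7-fold (95% counting interval 24.5 to 355) higher and Lck at -1.13 ± 0.26. Of 9 dendritic cell markers 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Batf3 at 5.44 ± 0.77, Cd24a at 3.33 ± 0.33 and Xcr1 at -3.05 ± 0.59. Of 4 epithelial markers 2 rose (2 adjusted over the list alone), with the tight junction gene Tjp3 at 1.05 ± 0.23, and this list was too short for the list test. Of 12 alternative activation genes 6 rose (7 adjusted over the list alone), with the lectin gene Mgl2 (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550) 169.9-fold (95% counting interval 30.0 to 6754) and Ccl24 36.5-fold (95% counting interval 12.1 to 180.1) higher. The list tests of fibroblast, lymphoid, dendritic and alternative activation genes gave adjusted p-values of 7.47e-04, 0.00869, 0.0534 and 7.63e-04, and adjusted p = 0.420, 0.494, 0.434 and 0.431 with an estimated correlation.

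Of 20 histone deacetylase and corepressor genes 1 rose, Hdac7 (1.88 ± 0.38), and 2 fell, Hdac8 (-0.72 ± 0.19) and Mta2 (-0.61 ± 0.15), with 1 and 2 adjusted over the list alone and 2 and 4 with the block. Of the targets of MS-275, Hdac1 had -0.01 ± 0.25 (adjusted p = 0.986), Hdac2 0.03 ± 0.16 (0.933) and Hdac3 -0.15 ± 0.16 (0.597). Of 22 genes commonly raised by such inhibitors 4 rose and 1 fell (5 and 1 adjusted over the list alone, replicate block 7 and 2), with the linker histone gene Hist1h1c at 3.93 ± 0.71, Tubb3 at 2.84 ± 0.36 and Cdkn2c at -0.86 ± 0.20. The cell cycle inhibitor gene Cdkn1a had 0.01 ± 0.39 (adjusted p = 0.996). The list tests gave adjusted p-values of 0.314 and 0.244. Of 29 cholesterol synthesis genes 3 fell (2 adjusted over the list alone, replicate block 10), with Acat2 at -1.69 ± 0.40 and Fdps at -0.94 ± 0.23. Of 27 stress response genes 5 fell (4 adjusted over the list alone, replicate block 10 with 1 higher), with Chac1 at -2.29 ± 0.56 and Shmt2 at -1.95 ± 0.30. For these lists the adjusted p-values were 0.00715 and 0.00225, and adjusted p = 0.795 and 0.337 with an estimated correlation.

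MS-275 in uninfected cells changed 2980 genes, 1801 higher and 1179 lower, of which 1602 and 655 changed at least 2-fold. With the replicate block 5652 were called, 2977 higher and 2675 lower. Large rises outside the lists, each from 0 counts, were those of Cd7 (ENSMUSG00000025163, chromosome 11, 121036747 to 121039418), a T cell surface protein gene (at least 174-fold), the cytoskeletal linker gene Ppl (at least 158-fold), Rhpn1 (at least 98.0-fold) and Rab44 (at least 62.6-fold). Of 4 measured RNA quality genes 1 rose (1 adjusted over the list alone, replicate block 2), with all 4 above 0 and a median of 1.43. The count of calls was 1436 and 1360 without IFN-γ replicate 1 and 2, and 1284 without replicate 2 and 1854 without replicate 1 of MS-275 plus IFN-γ. Of the 39 called genes named here 15 lost their call without some library: H2-Aa, Ciita, Il27, Tnfsf9, Hdac7, Hdac8, Mta2, Hist1h1c, Cdkn2c, Acat2, Fdps, Chac1, Lck, Tjp3 and Xcr1.

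MS-275 in infected cells asks whether the inhibitor changes the response of cells that carry the parasite. Ciita rose by 1.803 ± 0.355 (adjusted p = 0.0161), from 6.34 ± 2.26 to 22.03 ± 8.80 CPM (mean ± SD, n = 2), which is below the 55.2 ± 6.76 CPM of uninfected IFN-γ-treated cells. H2-Aa rose by 3.81 ± 1.04 (adjusted p = 0.0495) and H2-Oa by 2.36 ± 0.40, and 5 of 16 class II genes were higher (9 adjusted over the list alone, replicate block 11 with 1 lower). The class II list test gave an adjusted p of 0.00219, and adjusted p = 0.662 with an estimated correlation. The GTPases did not pass as a list (adjusted p = 0.755), with 1 of 22 called (0 adjusted over the list alone by edgeR, replicate block 3). Log2 fold changes were 0.68 ± 0.72 for Igtp (adjusted p = 0.610), -0.69 ± 0.60 for Irgm1 (0.519), 0.53 ± 0.58 for Gbp2 (0.624) and -0.52 ± 0.55 for Nos2 (0.611).

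Of 40 antiviral genes 11 fell with MS-275 in infected cells (19 adjusted over the list alone, replicate block 23), including Slfn8 (-1.78 ± 0.20) and Slfn2 (-1.63 ± 0.42). Of 45 cell cycle genes 10 fell (22 adjusted over the list alone, with 1 higher, replicate block 34 and 1), with a median of -1.37, Nusap1 at -1.99 ± 0.52 and Cdk1 at -1.74 ± 0.33. Of 27 stress response genes 4 fell (4 adjusted over the list alone, replicate block 10), with the one-carbon enzyme genes Mthfd2 at -1.15 ± 0.23 and Shmt2 at -1.14 ± 0.30. Their list tests gave adjusted p-values of 1.83e-09, 4.01e-10 and 0.00215, and adjusted p = 0.550, 0.587 and 0.337 with an estimated correlation. The inhibitor response list had 3 higher members of 22 (4 adjusted over the list alone, replicate block 8 with 1 lower, list test adjusted p = 0.314), with Hist1h1c at 3.36 ± 0.70 and Tubb3 at 2.45 ± 0.37. Of the 20 deacetylase genes edgeR called 0 (5 lower with the block, list test adjusted p = 0.221).

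Listed markers of other lineages also moved in infected cells, most of those called being higher. Thy1 was higher 491-fold (95% counting interval 168 to 2385). Of 13 fibroblast markers 7 rose (8 adjusted over the list alone), with Cav1 at 2.93 ± 0.69. Of 6 lymphoid markers 3 rose and 1 fell (5 and 1 adjusted over the list alone, replicate block 5 and 1), with Cd5 at 5.35 ± 0.38 and Lck at -1.41 ± 0.26. Of 9 dendritic cell markers 4 rose (5 adjusted over the list alone with 1 lower, replicate block 5 and 1), with Batf3 at 5.86 ± 0.79 and Itgax at 2.16 ± 0.58, and of 4 epithelial markers 1 rose, Tjp3 (1.75 ± 0.24; 3 adjusted over the list alone, replicate block 3). Of 12 alternative activation genes 5 rose (5 adjusted over the list alone, replicate block 8), with Mgl2 at 5.79 ± 0.65 and Ccl24 at 4.98 ± 0.43. The list tests of fibroblast, lymphoid, dendritic and alternative activation genes gave adjusted p-values of 3.09e-06, 0.00139, 0.0461 (block 0.0556) and 0.00125, and adjusted p = 0.337, 0.431, 0.431 and 0.431 with an estimated correlation.

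Large rises outside the lists with MS-275 in infected cells, each from 0 counts, were those of Ppl (at least 144-fold), Rab44 (at least 124-fold), the potassium channel gene Kcnh3 (at least 126-fold) and Cd7 (at least 66.5-fold). The largest falls picked by the same rule were those of Slfn1 (-3.46 ± 0.56), the checkpoint receptor gene Pdcd1 (-2.86 ± 0.53), the chemokine receptor gene Ccr2 (-2.63 ± 0.24), and the replication genes Recql4 (-2.55 ± 0.59) and Mcm10 (-2.54 ± 0.47). In all 1617 genes were called, 1247 higher and 370 lower, of which 1157 and 185 changed at least 2-fold (1699 and 445 with the block). The replicate block gave 4384 calls, 2496 higher and 1888 lower (77.1% higher without and 56.9% with the block). Upper-quartile normalization gave 1354 higher and 220 lower. Of 4 measured RNA quality genes 1 rose (1 adjusted over the list alone, replicate block 2), with a median of 0.35. The count of calls was 516 and 816 without replicate 1 and 2 of IFN-γ plus T. gondii, and 561 without replicate 2 of MS-275 plus IFN-γ plus T. gondii. Of the 35 called genes named here for this comparison 21 lost their call without some library: Cd7, Pdcd1, Recql4, Mcm10, H2-Aa, H2-Oa, Ciita, Slfn2, Hist1h1c, Nusap1, Cdk1, Mthfd2, Shmt2, Cav1, Lck, Itgax, Ly6c1, Fam131b, Rab39, C1rl and Ubash3b.

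Both MS-275 comparisons called 1050 genes higher and 265 lower in common, against 162 and 31.4 for independent lists, and 0 genes in opposite directions by edgeR. With the block they called 1953 and 1334 in common, against 535 and 364, and 19 in opposite directions. Their log2 fold changes correlated across genes, which are not independent replicates, at 0.857, with a covariance of 1.89 against -0.0012 in simulated data with no effects. The 2 comparisons share no library.

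Infection in cells treated with MS-275 asks the same question as infection without it, in inhibitor-treated cells. Cell cycle genes were higher in infected cells here: 22 of 45 members rose (39 adjusted over the list alone, replicate block 39), with a median of 2.11, and the helicase subunit genes Mcm3 and Mcm4 rose by 3.26 ± 0.35 and 3.09 ± 0.41. Of 29 cholesterol synthesis genes 7 rose (19 adjusted over the list alone, replicate block 21), with Acat2 at 2.64 ± 0.41 and Insig1 at 2.05 ± 0.32. Csf2 rose by 8.34 ± 0.44 (adjusted p = 9.82e-04), to 33.9 ± 3.81 CPM (mean ± SD, n = 2). These 2 lists gave adjusted p-values of 7.24e-19 and 3.07e-09, and adjusted p = 0.434 and 0.566 with an estimated correlation.

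Some of the GTPases and a few antigen presentation genes, induced by IFN-γ, fell with infection in MS-275-treated cells. The antiviral and chemokine lists, also induced by IFN-γ, did not pass as lists. Of 40 antiviral genes 3 rose and 1 fell (4 and 10 adjusted over the list alone, replicate block 6 and 12, list test adjusted p = 0.197), and of 32 chemokine and cytokine genes 6 rose and 1 fell (8 and 2, replicate block 10 and 6, list test adjusted p = 0.106). Of the 22 GTPases 8 fell (19 adjusted over the list alone, replicate block 22), with F830016B08Rik at -3.54 ± 0.68 and Gbp6 at -2.75 ± 0.55. Igtp had 2293 ± 323 CPM uninfected and 411 ± 361 CPM infected, a log2 fold change of -2.48 ± 0.75 (adjusted p = 0.108, block 0.00542), and Irgm1 one of -2.37 ± 0.63 (adjusted p = 0.0765, block 0.00511). Nos2 had 212 ± 57.4 and 267 ± 226 CPM (0.33 ± 0.55, adjusted p = 0.804). Of 16 class II genes 1 fell (2 adjusted over the list alone, replicate block 11), Ciita (-2.94 ± 0.36). Of 22 class I genes 2 fell (2 adjusted over the list alone, replicate block 14), Nlrc5 (-1.71 ± 0.23) and the peptidase gene Erap1 (-0.94 ± 0.18). Of 25 interferon signalling genes 4 fell (9 adjusted over the list alone, with 1 higher, replicate block 11 with 1 higher), with Stat3 at -1.33 ± 0.21. Of 20 costimulation genes 2 fell and 1 rose (4 and 1 adjusted over the list alone, replicate block 8 and 2), with the adhesion gene Icam1 at -1.72 ± 0.32, Havcr2 at -1.07 ± 0.17 and Cd80 at 1.32 ± 0.23. The list tests gave adjusted p-values of 5.28e-15, 5.20e-05, 1.99e-05, 8.79e-05 and 0.0218, and adjusted p = 0.431, 0.597, 0.640, 0.566 and 0.620 with an estimated correlation.

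The genes picked for large rises with infection under MS-275, chosen in the same way, were, besides Csf2, Acta1 (259.6-fold (95% counting interval 46.2 to 10293)), the chemokine gene Ccl7 (5.92 ± 0.84), Tnc (5.71 ± 1.01) and Xirp1 (5.18 ± 1.05). The rise of Xirp1 may not be separate from Cx3cr1, within which it lies on the same strand. Picked for large falls by the same rule, which leaves out F830016B08Rik above by its symbol, were, besides Ciita, Tigit (-3.82 ± 0.79), Ly6c1 (-3.57 ± 0.61), BC023105 (-3.03 ± 0.49) and Cxcl9 (-2.93 ± 0.54). BC023105 is annotated as a processed pseudogene, which the rule did not leave out because its symbol does not show it. Clec9a also fell (-2.70 ± 0.46), as did Tubb3 (-1.83 ± 0.35) and Klf6 (-1.12 ± 0.25) of the inhibitor response list, where 2 of 22 members were lower (2 adjusted over the list alone, replicate block 5 with 2 higher). In all 501 genes were called, 369 higher and 132 lower, of which 332 and 109 changed at least 2-fold (830 and 438 with the block). With the replicate block 2969 were called, 1681 higher and 1288 lower (73.7% higher without and 56.6% with the block), and DESeq2 called 1415. The count was 146 without control replicate 1 or 2, 266 and 225 without IFN-γ replicate 1 and 2, 3 and 35 without replicate 1 and 2 of MS-275 plus IFN-γ, and 33 without replicate 1 of the infected group. Csf2 and Mcm3 kept their call without each library, and the other 23 called genes named here lost it without some library. Both infection comparisons called 51 genes higher and 22 lower in common, against 2.63 and 0.342 for independent lists (542 and 515 with the block, against 125 and 88.6). They share no library.

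**Figure D3:**
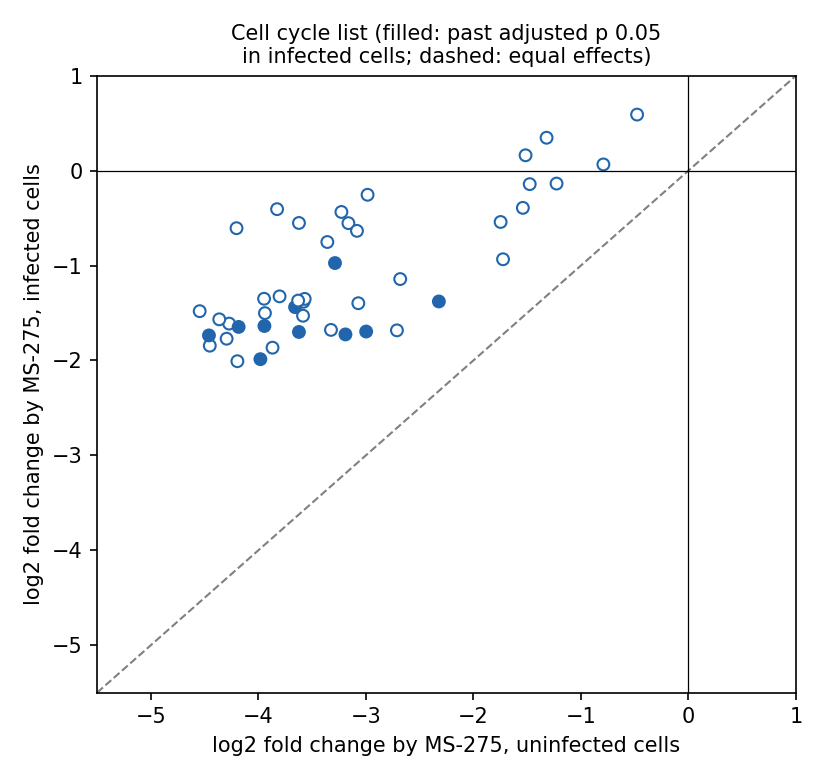
Log2 fold change with MS-275 of the 45 measured cell cycle genes in uninfected cells (horizontal axis) and infected cells (vertical axis). All 45 points lie above the dashed line of equal effects.

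The last comparison asks whether the effect of MS-275 differed between infected and uninfected cells. Chaf1b (ENSMUSG00000022945, chromosome 16, 93883901 to 93906115), a subunit of the chromatin assembly factor that deposits histones at replication forks, differed by 2.66 ± 0.24 (adjusted p = 0.0372). It went from 33.1 ± 0.591 to 5.56 ± 0.163 CPM with MS-275 in uninfected cells and from 38.1 ± 5.44 to 40.3 ± 2.89 CPM in infected cells (mean ± SD, n = 2). Of the cell cycle genes edgeR called 0 over all genes, 36 of 45 adjusted over the list alone and 20 with the replicate block, with a median difference of 2.22. Cdk1 had 71.7 ± 7.54 CPM without and 21.5 ± 11.7 CPM with MS-275 in infected cells. The list test gave an adjusted p of 6.52e-37, and adjusted p = 0.420 with an estimated correlation. Antiviral genes had a median difference of -0.82, with 7 of 40 lower adjusted over the list alone, 0 over all genes by edgeR and 5 with the block (list test adjusted p = 5.38e-11, and 0.499 with an estimated correlation). Over all genes 1 was called, with 821 at an unadjusted p under 0.05, and 181 with the replicate block, 147 higher and 34 lower. DESeq2 called 148. Chaf1b lost its call without each library except replicate 2 of MS-275 plus IFN-γ plus T. gondii, without which edgeR called 60 genes, and without each of the others 0, with 556 to 1304 genes at an unadjusted p under 0.05 over all left-out libraries.

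Genes induced at least 2-fold by IFN-γ were then followed through infection and MS-275. There were 878 of them (1178 with the replicate block), and 326 genes were repressed as much (701 with the block). Infection lowered 28 and raised 19 of the induced genes (392 and 93 with the block), against 0 and 0 in each of 20 simulated data sets with no effects, analysed with edgeR. In uninfected cells MS-275 raised 145 and lowered 95 of them (326 and 221 with the block). In infected cells MS-275 raised 103 and lowered 67 (269 and 192 with the block). Infection in MS-275-treated cells lowered 84 and raised 20 (464 and 62 with the block). DESeq2 called 228 of the induced genes lower with infection. Both MS-275 comparisons raised 89 of them (230 with the block). Without a single library the number lowered by infection ran from 0 to 118, with 0 without IFN-γ replicate 1 or 2 and without IFN-γ plus T. gondii replicate 1, and 118 without its replicate 2. The number raised by MS-275 in infected cells ran from 31 without control replicate 1 to 123 without replicate 1 of MS-275 plus IFN-γ plus T. gondii.

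Induced genes that infection lowered and MS-275 raised in infected cells numbered 7, against 3.28 for independent lists within the induced genes. Of the induced genes lowered by infection edgeR called 0 as lowered further by MS-275. With the replicate block the numbers were 89, 89.5 for independent lists, and 41, and DESeq2 found 45. Both comparisons share the IFN-γ plus T. gondii libraries. The covariance of their log2 fold changes was 0.0957, against a mean of -0.165 in simulated data with no effects and -0.155 in simulated data with infection as the only effect besides IFN-γ. The latter had a mean of 263.9 induced genes lowered by infection, and edgeR called 0 of these as raised by MS-275 in each of 20 data sets, against 7 of 28 here (89 of 392 with the block). They held no MS-275 effect and no pool effect, so what the shared libraries add among genes that MS-275 does raise stays open. The 7 genes and their log2 fold changes with MS-275 in infected cells were Ly6c1 (4.55 ± 0.80; chromosome 15, 75044018 to 75048830), Fam131b (2.53 ± 0.58), the leukotriene receptor gene Ltb4r1 (1.93 ± 0.29), Ciita (1.803), Rab39 (1.65 ± 0.32), C1rl (1.35 ± 0.21) and Ubash3b (0.87 ± 0.19). Without a single library the number ran from 0 without IFN-γ replicate 1 or 2 or IFN-γ plus T. gondii replicate 1 to 17 without IFN-γ plus T. gondii replicate 2.

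In the authors' deposited table of IFN-γ against control 2338 genes were listed, 1440 higher and 898 lower, and all 2338 had the same sign here. Of the 1542 genes called here 1518 were in the authors' deposited table (2333 of 4230 with the block), and the log2 fold changes correlated across its genes at 0.970. The authors' deposited table of MS-275 plus IFN-γ against IFN-γ listed 3548 genes, 2224 higher and 1324 lower. Of these 3447 were tested here, all with the same sign, 2945 of the 2980 genes called here were in that table (3443 of 5652 with the block), and the correlation was 0.960. The smallest absolute log2 fold change listed was 0.501 in the first table and 0.502 in the second. Calls here had no minimum fold change, so genes called here with smaller changes were not in those tables. Both tables come from the same counts and are not independent evidence.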

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

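Tests chosen only after the result was seen were those of an infection effect with or without MS-275, of a weaker IFN-γ response in replicate 1, of fibroblasts and of the count filter. The values here drew attention because the effect of MS-275 differed between infected and uninfected cells by a test of the difference itself. Chaf1b differed by 2.66 on the log2 scale. Of the gene lists, the difference had a median of 2.22 for cell cycle, 0.64 for cholesterol synthesis (adjusted p = 1.16e-07), -0.82 for antiviral genes, -0.50 for the GTPases (0.0155), -0.55 for chemokines and cytokines (0.0160, and 0.0540 with the block), -0.63 for costimulation (0.00715) and -0.32 for early NF-κB targets (0.00631). With an estimated correlation the adjusted p-values of cholesterol, GTPase, chemokine, costimulation and NF-κB lists were 0.597, 0.778, 0.681, 0.566 and 0.640, so none passed. The 4 measured RNA quality genes, too few for a list test, had a median difference of -1.07, with all 4 below 0, and whether RNA quality bears on the lists was not tested.

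The fall of cell cycle genes under MS-275 was smaller in infected cells. A single pool of libraries does not account for it, since the median difference was 2.43 and 1.52 in the pools of replicates 1 and 2, with 45 of 45 members above 0 in each. Infection alone did not raise these genes, with medians of -0.19 and -0.13 without MS-275 against 2.24 and 1.44 with it. The 500 other genes with the largest effect also responded more weakly to MS-275 in infected cells. Their median ratio of the effect in infected to that in uninfected cells was 0.767 (95% bootstrap interval over genes 0.737 to 0.799). This weakening was smaller than that of the cell cycle genes, so a weaker response of all genes is argued against only as the whole cause. Over the 200 genes outside the list that MS-275 lowered most, however, the ratio was 0.443 (0.422 to 0.464), near the 0.377 of the cell cycle genes, so a weaker response of lowered genes in general may be part of the pattern and stays open, as do effects of the parasite on proliferation or on the inhibitor, which were not tested.

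IFN-γ-induced transcripts were lower in replicate 1 than in replicate 2 of both infected groups, by a median of -0.43 without and -0.42 with MS-275 over the 878 induced genes. A weaker IFN-γ response in the replicate 1 pool is argued against by the uninfected libraries, where the gap was -0.0032 and -0.0068, at most 0.0161 of that in infected libraries. A stronger infection in the replicate 1 libraries is a candidate explanation: the 200 genes outside the induced set that infection raised most also rose more in replicate 1, by a median of 0.61 (0.51 to 0.72) without and 0.44 (0.34 to 0.56) with MS-275. Parasite load was not measured here.

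The measured marker genes of other lineages, 32 of 71 listed, were higher as a set with MS-275, although Lck fell in both comparisons. A rise shared by all genes of the same low baseline was examined as the whole cause with random lists matched on level. The marker median lay at the 99.83 percentile of 10000 matched random lists in uninfected cells and at the 99.32 percentile in infected cells. The matched lists themselves had medians of 1.22 and 1.04, against 2.78 and 2.13 for the markers, so part of the rise was shared. The count filter as the whole cause was examined in the same way. Over the 18 markers that pass it on the 6 libraries without MS-275 the medians were smaller, at 1.14 uninfected and 0.892 infected. They lay at the 99.79 and 99.49 percentile, with matched lists at medians of 0.22 and 0.15. The markers thus rose more than matched genes. Random lists treat genes as independent, however, and none of the marker list tests passed with an estimated correlation, so the percentiles settle neither cause. Fibroblasts would bring collagen transcripts, yet summed collagen counts stayed below those of Thy1 in each of the 4 MS-275 libraries, with a largest upper 95% bound of the ratio of 0.268. Collagen was not absent, however. Col1a1 had 2.97 ± 1.61 CPM with MS-275 against 0.18 ± 0.0058 without it in uninfected cells (mean ± SD, n = 2). In infected cells Col1a1 had 2.07 ± 0.157 against 0.37 ± 0.119 CPM. T cells would bring Cd3 chain transcripts. Cd3 chain counts were 0.071 and 0.056 of those of Cd7 in replicates 1 and 2 of MS-275 plus IFN-γ (upper bounds 0.125 and 0.093). This argues against T cells as the source of Cd7 in these 2 libraries. The ratios were 0.545 and 0.25 in those of MS-275 plus IFN-γ plus T. gondii (upper bounds 1.15 and 0.364), where Cd7 had 22 and 140 counts. There T cells cannot be told apart from a change in the RAW264.7 cells themselves. Cells of further types were not tested. A direct effect of the inhibitor on silent genes is thus a hypothesis that these tests leave open.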

How the results depend on the processing

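One alternative, leaving out the first library of both infected groups, was chosen after seeing the data. Over the 181 gene and comparison pairs named in the text, 2982 of 3619 alternative values kept direction and side of the threshold, 593 kept direction and were no longer called, 22 were newly called and 22 changed sign. The replicate block left 174 of 181 on the same side and newly called 6, changing no other call of a named gene, and DESeq2 left 177 on the same side and newly called 3. A library left alone in its group is assumed to vary like those of the other groups. With 2 libraries per group, 4 of 50 simulated 2-fold changes were found by edgeR without a pool effect and 0 of 50 with one (4 of 50 with the block, and 31 of 50 at 8-fold without it). These shares do not carry over to the data, where 2980 genes were called for the contrast simulated, but changes of that size may be missed. The lower depth of MS-275 plus IFN-γ plus T. gondii replicate 1 limits genes with few counts.

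Counts of calls that moved by over 1.5 times are given in the order of IFN-γ, infection without MS-275, MS-275 in uninfected cells, MS-275 in infected cells, infection with MS-275, and the difference between both MS-275 effects, where the counts were 1542, 135, 2980, 1617, 501 and 1. With the replicate block they were 4230, 1987, 5652, 4384, 2969 and 181, which comes with the removal of variation shared within a pool. At an adjusted p of 0.01 they were 624, 1, 1252, 442, 19 and 0 by edgeR. DESeq2 called 2383 for IFN-γ, 955 and 1415 for infection without and with MS-275, and 148 for the difference. In simulated counts without a pool effect DESeq2 made 26 false calls against 4 by edgeR, so some of its added calls may be false. With no filter on low counts the numbers were 2535 for IFN-γ, 1259 and 1634 for infection without and with MS-275, 2766 for MS-275 in infected cells and 342 for the difference. With at least 5 CPM in 2 samples they were 1954 and 775 for MS-275 in uninfected and infected cells and 3 for the difference, with fewer genes tested. With only the groups compared, and so fewer samples, edgeR called 0 for infection without MS-275 (1541 at an unadjusted p under 0.05), 603 for MS-275 in infected cells, 1 for infection with MS-275 and 0 for the difference (651 unadjusted). Without the first library of both infected groups it called 30, 725, 86 and 0 in the same order (430 unadjusted for the last). Upper-quartile normalization gave 3 genes for the difference, 78 higher and 23 lower for infection without MS-275, and 1354 higher and 220 lower for MS-275 in infected cells. It also shifted the median of all genes with MS-275 from 0.0059 to 0.11 in uninfected and from -0.01 to 0.09 in infected cells. Except where the block, a filter or the number of samples shows it, the cause was not tested.

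Induced genes lowered by infection, 28 in number, were 392 with the replicate block, 228 with DESeq2, 327 with no filter, 0 with only the groups compared, 5 without both first libraries and 0 at an adjusted p of 0.01. Those raised by MS-275 in infected cells, 103, were 269, 167, 258, 38 and 19 in the same order, without the setting of both first libraries, where the count stayed within 1.5 times. Those with both changes, 7, were 89, 45, 85, 0, 2 and 0, and 3 with upper-quartile normalization and 4 with at least 5 CPM in 2 samples. Counting any positive fold change as induced gave 30, 108 and 8. Of 132 gene list tests 56 passed, 54 with DESeq2 size factors, 50 with the replicate block and 0 with an estimated correlation. The cause was not tested.

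Leaving out each library in turn gave 455 to 1652 genes for IFN-γ, 1 to 521 for infection without MS-275, 1284 to 3085 for MS-275 in uninfected cells, 516 to 1436 for MS-275 in infected cells, 3 to 671 for infection with MS-275 and 0 to 60 for the difference by edgeR (556 to 1304 at an unadjusted p under 0.05). The induced genes lowered by infection ran from 0 to 118, those raised by MS-275 in infected cells from 31 to 123, and those with both changes from 0 to 17.

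Signs changed only in genes that were not called. For MS-275 in uninfected cells, Hdac1 had 0.0206 with DESeq2 size factors, 0.0893 with upper-quartile normalization, 0.0613 with at least 5 CPM in 2 samples, 0.0177 with DESeq2, 0.0049 with only the groups compared, and -0.0459 to 0.0749 over left-out libraries. Hdac2 had -0.0464 to 0.15 over left-out libraries, and Cdkn1a -0.0069 with no filter, -0.0200 with the replicate block and -0.49 to 0.42 over left-out libraries. For MS-275 in infected cells the values over left-out libraries were -1.83 to 0.17 for Nos2, -1.65 to 0.47 for Irgm1, -0.72 to 1.97 for Igtp and -0.42 to 1.44 for Gbp2. For infection, Cxcl10 had -0.0213 to 0.93 without MS-275 over left-out libraries, and Nos2 -0.98 to 1.00 with MS-275, and -0.98 without both first libraries. The cause was not tested.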

Other observations

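Glycolysis, lysosome and apoptosis genes had few calls without the block and more with it. With IFN-γ 3 of 26 apoptosis genes rose and 2 fell (11 and 5 adjusted over the list alone, replicate block 12 and 7, list test adjusted p = 0.144). With MS-275 in uninfected cells 4 of 30 glycolysis and hypoxia genes rose (4 adjusted over the list alone, replicate block 9, list test adjusted p = 0.0741). Of 39 lysosome and autophagy genes 3 rose and 1 fell (3 and 0 adjusted over the list alone, replicate block 17 and 5, list test adjusted p = 0.331). Of the apoptosis genes 0 rose and 0 fell by edgeR with infection in MS-275-treated cells, 6 were lower adjusted over the list alone and 8 with the block. That list test gave an adjusted p of 0.0332 (block 0.0662), and adjusted p = 0.640 with an estimated correlation. Among the 4 measured RNA quality genes, too few for a list test, 1 was lower with IFN-γ, those higher with MS-275 are given in the report, and with infection in MS-275-treated cells all 4 were below 0, with a median of -0.73.

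Xrcc5 (ENSMUSG00000026187, chromosome 1, 72307421 to 72394952), a subunit of the Ku DNA repair complex, had raw counts of 2 and 7 in the libraries with IFN-γ alone, against 262 and 308 in control cells, 230 and 281 with IFN-γ and T. gondii, 173 and 231 with MS-275 and IFN-γ, and 435 and 656 with all of these. An error in the count table was not tested, so the fold changes of Xrcc5 are uncertain.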
